A study of Sus scrofa with 9 samples.

How the data were processed

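Whole blood was collected in PAXgene tubes, which fix RNA at sampling, and RNA was isolated with the matching kit, per the labels' protocols. From 0.5 µg of RNA, Cy3-labelled cRNA was made with Agilent's one-colour linear amplification kit, and each sample was hybridised to 1 array of a porcine design. The file headers name Feature Extraction 10.5.1.1 and the submitters' processing notes name 9.5.3.1; which is right was not settled. The 9 scanner files hold processed spot intensity, which per the file headers is background-subtracted and not normalized between arrays, and the raw mean and background intensity of each spot. The deposited series-wide values hold intensity on a linear scale; how the authors made it is not given in the sources used here. Its 9 columns share 1 maximum, have a median of 11.4 each on that linear scale and follow the ranks of their own arrays, as quantile normalization would leave them. Its scale was read as linear from the values and used as an alternative.

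Control spots and spots marked as outliers were left out, spots of a probe were averaged, and 7 probes with no usable spot on some array were dropped, leaving 43596. Main values were log2 processed signal minus each array's 75th percentile. Probes well above background on all 3 arrays of at least 1 group were tested, 19783 in all; 15803 were well above background on all 9. A probe not well above background on any array of a group is given as "at least N-fold": the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. Symbols came from the files' gene name column, from descriptions and from RefSeq accessions matched to the given tables, for 3825 of 43603 probes and 2609 symbols; other probes are unnamed here. No genome was used, so positions were not analysed here. For a gene with several probes the tested one with the highest mean was used.

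All 9 arrays entered 1 limma fit (version 3.58.1, R 4.3.3) with group as the only term, 6 residual and 4.6 prior degrees of freedom, and a threshold of 0.05 on the Benjamini-Hochberg adjusted p. Before the data were examined, 33 gene lists were fixed, covering blood cell types, the respiratory chain and stress, immune and metabolic processes. Of their 947 genes 369 have a named probe; 27 lists had 5 or more tested genes and were tested with camera at its preset correlation of 0.01 among 1580 named genes, beside camera with an estimated correlation and fry. Camera compares a list with the other named genes. By limma's fry, which asks whether a list's genes move one way on balance, 11, 3 and 1 lists passed at 6 h, at 24 h and at 24 h against 6 h; 9, 2 and 0 of these were also camera calls.

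The named genes follow a rule also fixed beforehand: up to 8 genes per direction with the largest change past the threshold or, where fewer than 3 passed, the 5 with the smallest unadjusted p, given as values that did not pass, and up to 2 members per list and direction. No named gene passed over all 19783 probes in any comparison. Of the list members, those with an unadjusted p under 0.05 were eligible for the text, a restriction made after the values were seen, and the text gives a part of them. The values of some genes are not reported here.

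On simulated data with the real probe means and spreads, limma recovered 46.6% of probes changed by 2 on the log2 scale and 1.6% of those changed by 1, for 6 h against before feeding with 19783 probes. Simulated noise was independent between probes, which the real noise is not. Alternatives were other scalings (quantile, median, spike-in, normexp with an offset of 50, the deposited series-wide values), other filters, other fits, a replicate block, leaving out each array and fitting only the arrays compared. Random probe sets were matched to a list on mean signal in 200 bins of the tested probes, 10000 sets each. They left out the probes used for the list, but could hold other or unnamed probes of the same genes. After seeing the data, that fine match replaced one in 10 bins of named genes, and a percentile over probes above background on all arrays and limma array weights were added. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and the data.table package (version 1.17.8), were used to join files and draw plots.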

Results

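The series measured RNA in whole blood of male Clawn miniature pigs, a small laboratory breed, around a single oral dose of azide. Azide is a poison that blocks cytochrome c oxidase, the last enzyme of the mitochondrial respiratory chain. The dose was 300 µg/kg, which the design text gives as 0.01 of the LD50; the salt was not stated. Blood was taken before feeding (0 h) and at 6 h and 24 h after it, with 3 arrays at each time and 9 in all. The labels give the age as 7 months in one field and 7 weeks in another. They do not say whether arrays with the same replicate number came from one animal, so p-values measure the spread between these samples. No untreated pigs were sampled at 6 h or 24 h, so feeding, fasting, handling and time of day are not separated from the dose. Each group lay on its own slide and scan, so slide and group cannot be told apart.

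Each array held 43803 non-control spots, of which 39.9% to 46.6% were well above background before feeding, 42.4% to 47.8% at 6 h and 45.5% to 56.6% at 24 h. The 24 h arrays were brighter before scaling: the log2 75th percentile was 6.83, 6.78 and 7.70 there, against 6.36, 5.80 and 6.56 before feeding. The number of arrays, 3 per group, limits the precision of every value. Changes below are log2 differences of group means with the limma standard error (SE, n = 3 per group), and adjusted p-values are from limma with Benjamini-Hochberg adjustment over 19783 probes unless said otherwise. Only 8.77% of the probes could be given a gene symbol, so named genes are a small part of what was measured.

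**Figure D1:**
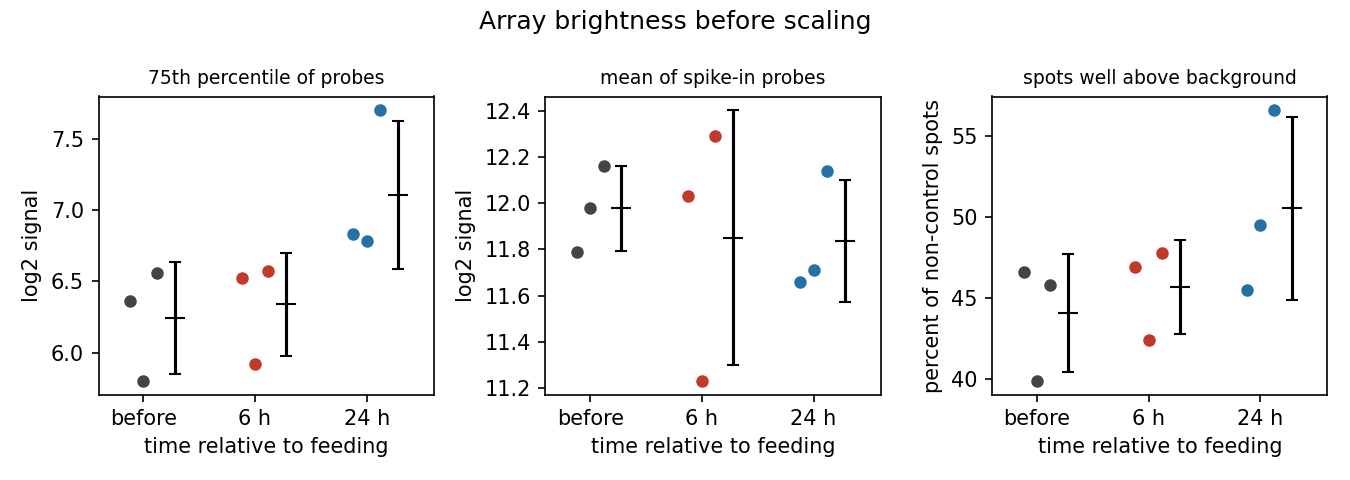
Brightness of each array before scaling (points, 3 arrays per time; bars, mean and SD), as the log2 75th percentile of non-control probes, the log2 mean of the spike-in control probes and the percent of spots well above background. The third 24 h array was the brightest, at 7.70 on the log2 scale, while its spike-in mean of 12.14 lay within the range of the other arrays.

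The first comparison, 6 h against before feeding, asks what differed in blood soon after the dose. Transcripts of neutrophils and monocytes were higher at 6 h and those of T cells, ribosomal proteins, complex I, cytochrome c oxidase and ATP synthase lower, by camera with a small fixed correlation between genes. None of these calls held when that correlation was estimated (adjusted p = 0.404 to 0.443 with an estimated correlation). The estimates ran from 0.01 for complex I to 0.50 for neutrophil markers. Rounded, the complex I estimate equals the preset, so a clearly larger correlation did not end that call. By fry, 9 of the 11 camera calls at 6 h also passed, all but those of T cell and dividing cell markers. Lactoferrin (LTF), a neutrophil granule protein, differed by 4.50 ± 0.81, and haptoglobin (HP), which binds free haemoglobin, by 5.34 ± 1.33. HSP70.2, a heat-inducible chaperone, differed by 4.53 ± 0.88. The 6 h arrays differed widely in these genes, with SDs of 2.11, 3.62 and 2.20; without 6 h replicate 3 the changes were 3.70 for LTF, 3.71 for HP and 3.41 for HSP70.2, and without 6 h replicate 2 they were 5.69, 7.29 and 5.60 and all 3 passed the threshold. With all 9 arrays no named gene passed the threshold over all probes: the adjusted p-values of these 3 were 0.0597, 0.0805 and 0.0633 by limma. Tested as 1580 named genes with one value each, 10 passed at 6 h, 9 of them higher. The values are given without a call for any single gene.

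Neutrophil markers had higher values for 7 of 7 tested genes (median 1.43, camera adjusted p = 8.66e-04), and 5 passed when adjusted over the list alone against 0 over all probes. Besides LTF, NCF1, a subunit of the phagocyte oxidase, was at a 5.64-fold higher level, with an SE of 0.53 on the log2 scale. Of 11 monocyte markers 10 were higher (median 1.75, camera adjusted p = 0.00234), 7 of them when adjusted over the list alone and 0 over all probes. CD14, a receptor for bacterial lipopolysaccharide, differed by 2.56 ± 0.57 and the lectin LGALS3 by 1.93 ± 0.34. Neither call held with an estimated correlation (adjusted p = 0.404 with an estimated correlation for neutrophil and 0.443 for monocyte markers).

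T cell markers had lower values for 9 of 10 genes (median -0.75, camera adjusted p = 4.15e-04), with 0 past the threshold when adjusted over the list alone and 0 over all probes. CD3G and CD3D, chains of the T cell receptor complex, differed by -1.80 ± 0.61 and -1.30 ± 0.45. This call was lost too (adjusted p = 0.404 with an estimated correlation), and by fry the adjusted p was 0.0590. All 7 tested T cell receptor probes named by their description had lower values, with a mean of -0.52 ± 0.23 (SE over arrays), while 22 immunoglobulin probes had a mean of -0.05 ± 0.27. KLRK1, an activating receptor of cytotoxic cells, differed by -1.98 ± 0.60. It was 1 of 3 tested NK and cytotoxic markers, all with lower values (median -0.75), too few for a list test. Among 7 dividing cell markers 6 had lower values (median -0.80, camera adjusted p = 0.00873), including STMN1, which destabilises microtubules, at -1.04 ± 0.32. That list had adjusted p = 0.443 with an estimated correlation and 0.127 by fry; 0 of its genes passed adjusted over the list alone and 0 over all probes.

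All 40 tested cytosolic ribosomal protein genes had lower values at 6 h (median -0.67, camera adjusted p = 2.89e-15), of which 10 passed when adjusted over the list alone and 0 over all probes. RPL17 differed by -1.30 ± 0.31 and RPS10 by -1.26 ± 0.24. The list had adjusted p = 0.404 with an estimated correlation. Subunits of the respiratory chain and ATP synthase went the same way. All 8 cytochrome c oxidase genes had lower values (median -0.88, camera adjusted p = 0.00149), with COX5A at -1.14 ± 0.28 the 1 gene past the threshold over the list alone. All 9 ATP synthase subunits had lower values (median -0.56, camera adjusted p = 0.00642), among them ATP5O at -0.84 ± 0.30. Of 12 genes in the complex I list 9 had lower values (median -0.34, camera adjusted p = 0.0242). Among them ND6 was at a 2.01-fold lower level, with an SE of 0.33 on the log2 scale. Each of these 3 lists had adjusted p = 0.404 with an estimated correlation, the complex I call also ended without 6 h replicate 2 (camera adjusted p = 0.0737), and 0 ATP synthase or complex I genes passed adjusted over the list alone. Of 4 tested subunits of complexes II and III, too few for a test, 3 had higher values (median 0.32).

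Stress hormone, cytokine and interferon lists were higher. All 8 glucocorticoid response genes had higher values (median 1.02, camera adjusted p = 0.00218), with TXNIP, an inhibitor of thioredoxin, at 2.01 ± 0.33 and ALOX5AP, needed for leukotriene synthesis, at 1.95 ± 0.44; 4 passed adjusted over the list alone. Of 17 inflammatory cytokine and NF-kB genes 14 were higher (median 0.93, camera adjusted p = 0.0141) and 3 passed over the list alone. The interleukin 1 receptor antagonist IL1RN differed by 2.06 ± 0.37 and the NF-kB inhibitor NFKBIA by 2.19 ± 0.47, while the chemokines CCL5 and CXCL10 were at -1.48 ± 0.56 and -1.83 ± 0.77. Of 18 interferon response genes 14 were higher (median 0.94, camera adjusted p = 0.0109) and 11 passed over the list alone, with the transcription factor IRF7 at 1.59 ± 0.37. None of the 3 held with an estimated correlation (adjusted p = 0.443 for each), and 0 of their genes passed over all probes. By fry all 3 passed, with adjusted p = 0.0429 for glucocorticoid, 0.0445 for cytokine and 0.0429 for interferon genes. The interferon call also ended with spike-in centring (camera adjusted p = 0.0574), without the third array before feeding (0.107) and without 6 h replicate 2 (0.0708). In the 3 arrays at 6 h the glucocorticoid level was 0.30, 0.29 and 1.51 and the cytokine level 0.17, 0.13 and 0.85, each highest where the neutrophil (1.12, 0.27 and 2.14) and monocyte (0.61, 0.25 and 1.55) levels were highest. The interferon level was 0.14, 0.55 and 0.38. Being highest in 6 h replicate 3 is not particular to the called lists. Heat shock and unfolded protein genes, which did not pass camera, were at 0.34, 0.06 and 1.76, while vascular tone genes were lowest there (0.21, 0.30 and -0.66).

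The other tested lists did not pass camera at 6 h, though by fry antigen presentation and immediate early genes did, as higher (adjusted p = 0.0429 for each). Their medians were 0.68 for heat shock and unfolded protein genes, 0.66 for glycolysis, 0.47 for hypoxia, 0.14 for oxidative stress and 0.61 for apoptosis genes. They were 0.93 for immediate early genes, 0.54 for platelet markers, 0.47 for eosinophil, basophil and mast cell markers, 0.17 for antigen presentation and 0.16 for vascular tone. Medians near or below 0 were 0.03 for the citric acid cycle, 0.07 for heme and iron genes, -0.08 for fatty acid oxidation, -0.18 for the mitochondrial ribosome, -0.21 for the proteasome and -0.36 for cholesterol genes. Single members stood out in value: HMOX1, which degrades heme, at 2.31 ± 0.72, SOD2, the mitochondrial superoxide dismutase, at 2.05 ± 0.57, the glucose transporter SLC2A1 at 1.04 ± 0.25 and CPT1A, which controls fatty acid entry into mitochondria, at 1.68 ± 0.37. In lists with under 5 tested genes, the medians were -0.45 for 2 B cell and plasma cell markers, -0.30 for 1 red cell precursor marker, 2.10 for 1 integrated stress response gene and 0.09 for 1 circadian clock gene.

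By limma 5 probes rose at 6 h and 0 fell; none has a gene symbol. All were not well above background on any array before feeding, so their changes are lower bounds, from at least 1.31-fold to at least 2.29-fold (adjusted p = 0.0343 for each). At an unadjusted p under 0.05 there were 5050 probes, against 989 by chance. No overlap between the groups was seen for 26.6% of probes, against 10% by chance. The share was 26.5% in each of the other comparisons, where 0 probes passed, so it is not particular to 6 h. Noise is not independent between probes, so a share over 10% is not by itself a change. The count of 5 rests on single arrays: it was 2697 without 6 h replicate 2, 9 without 24 h replicate 3, 2 without the second array before feeding and 0 without any one of the other 6. It was 659 with spike-in centring, of which 653 were higher, 8 with quantile normalization, and 0 with normexp, with no filter, and with a trend and robust fit. With the replicate number as a block it was 620, of which 537 were higher and 83 lower. Whether equal numbers come from the same animal is not known. Other splits of the 6 arrays gave up to 10 lists past the threshold, against 11 for the real groups.

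**Figure D2:**
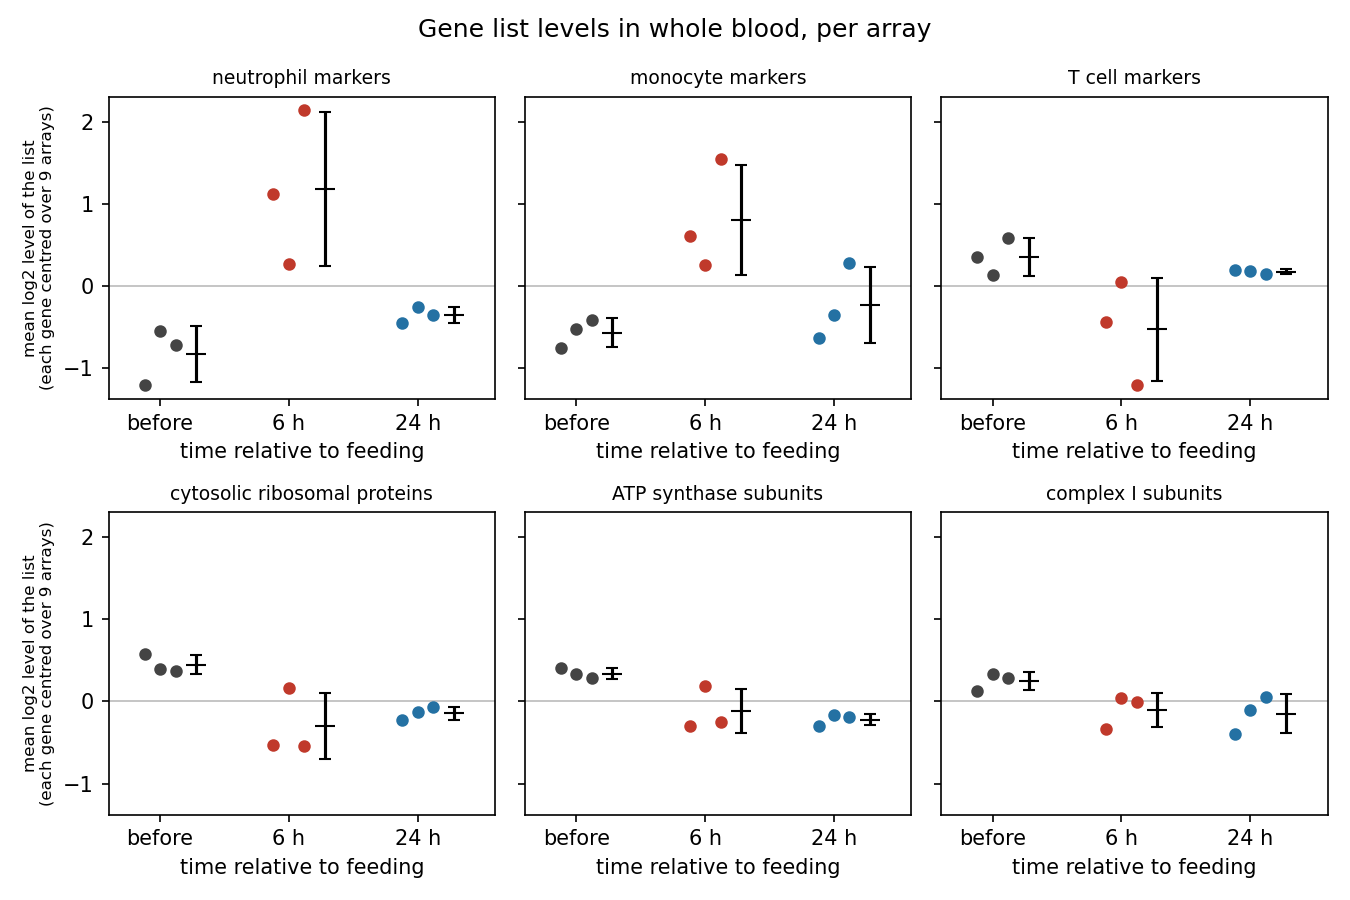
Mean log2 level of 6 gene lists in each array, each gene centred on its mean over the 9 arrays (points, 3 arrays per time; bars, mean and SD). At 6 h the neutrophil level was 1.12, 0.27 and 2.14 in the 3 arrays, against -1.21, -0.55 and -0.72 before feeding.

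The second comparison, 24 h against before feeding, asks what was still different a day later. Ribosomal protein genes were lower here too, with lower values for 38 of 40 (median -0.66, camera adjusted p = 3.99e-12). So were 9 of 9 ATP synthase subunits (median -0.56, camera adjusted p = 0.00262). All 12 of 12 genes in the complex I list were lower as well (median -0.32, camera adjusted p = 0.0143). This comparison shares its arrays before feeding with the first, so the repeat is not separate evidence that a change lasted. Adjusted p was 0.556, 0.529 and 0.529 with an estimated correlation, and 0 genes of the 3 lists passed adjusted over the list alone or over all probes. By fry the adjusted p was 0.12, 0.0498 and 0.0397. Antigen presentation also passed by fry, as lower (adjusted p = 0.0498, 9 of 13 genes lower), but not by camera (adjusted p = 0.169). Cytochrome c oxidase genes did not pass at 24 h, with 6 of 8 lower (median -0.46, camera adjusted p = 0.141). RPL35 differed by -1.02 ± 0.31, RPS21 by -0.92 ± 0.28, ATP5I by -0.88 ± 0.32 and NDUFS5 by -0.75 ± 0.23. These lists hold bright probes, and the brightest tested probes had lower values at 24 h. The brightest 1%, 198 in number, had a median of -0.65, against -0.05 at 6 h. The ribosomal list has a median signal percentile of 99, so these include part of it. Probes from the 95th to the 99th percentile of signal had a median of -0.27 at 24 h. Random probe sets of the same brightness had medians of -0.45 for the ribosomal list, -0.26 for ATP synthase and -0.13 for complex I. The ribosomal median was -0.14 after quantile normalization, where all 3 lists still passed (camera adjusted p = 0.0314, 0.0485 and 0.0314), and -0.12 on the deposited series-wide values, where none did (0.0553 for each). The complex I call also ended with no filter (0.0705), without the first array before feeding (0.0630) and without 24 h replicate 2 (0.0770). With arrays centred on the spike-in controls, which moves the median change of all probes to 1.00, the 3 medians turned to 0.35, 0.44 and 0.69. Camera compares a list with the other named genes, and under that centring 2 of the 3 calls were kept as lower. These were the ribosomal and ATP synthase lists, while the complex I call ended.

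Blood cell markers did not pass at 24 h. Medians were 0.43 for neutrophil, 0.25 for monocyte and -0.16 for T cell markers. CCR7, a homing receptor of naive T cells, was at -0.99 ± 0.37, and CXCR4, a chemokine receptor listed with the glucocorticoid response, at 1.13 ± 0.37. Of the genes with the smallest p-values, PSTK, an enzyme of selenocysteine synthesis, was at -2.11 ± 0.39 and the cyclin CCND2 at -1.56 ± 0.36. The centromere histone CENPA was at least 2.62-fold higher and CXCL8, a neutrophil attractant, at least 1.74-fold; both were not well above background before feeding, with adjusted p = 0.159 and 0.231 by limma. EDN1, the vasoconstrictor endothelin, was at least 1.52-fold higher (adjusted p = 0.249 by limma). CDC20, an activator of mitotic exit, was at -1.33 ± 0.45 and the embryonic globin HBE1 at -0.91 ± 0.39.

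By limma 0 probes passed at 24 h, with 2745 at an unadjusted p under 0.05 against 989 by chance and a smallest adjusted p of 0.101. Quantile normalization gave 6 probes and spike-in centring 5896, of which 5893 were higher; the number of lists was 6 without 24 h replicate 3 and 5 without 24 h replicate 1, 6 h replicate 3 or the second array before feeding. Other splits of the 6 arrays gave up to 4 lists, against 3 for the real groups.

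The third comparison, 24 h against 6 h, tests whether the change at 24 h differed from that at 6 h. It uses the same 6 h arrays as the first, so noise in them moves both comparisons, in opposite directions. A return at 24 h is therefore not separate evidence. Neutrophil markers were lower at 24 h for 7 of 7 genes (median -1.58) and monocyte markers for 11 of 11 (median -0.79), each with camera adjusted p = 0.00903, and 5 genes in each list passed adjusted over the list alone against 0 over all probes. T cell markers were higher for 9 of 10 genes (median 0.64, camera adjusted p = 0.00115). For each of the 3, adjusted p = 0.635 with an estimated correlation, and none passed by fry (adjusted p = 0.121, 0.121 and 0.169). The monocyte call also ended with normexp (camera adjusted p = 0.0548) and on the deposited series-wide values (0.0611). Bright probes were lower here too: random probe sets of the same brightness had medians of -0.43 for the neutrophil, -0.34 for the monocyte and -0.16 for the T cell list. LTF differed by -3.09 ± 0.81, LGALS3 by -1.49 ± 0.34, CD3G by 1.62 ± 0.61 and ICOS, a T cell costimulator, by 0.85 ± 0.30. The LTF value was -2.29 without 6 h replicate 3, and without 6 h replicate 2 it was -4.28 and passed the threshold.

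Genes of cholesterol synthesis and uptake were higher at 24 h than at 6 h for 5 of 6 (median 0.83, camera adjusted p = 0.0133), a call kept in 17 of 24 alternatives. It ended with normexp (camera adjusted p = 0.0548), the deposited series-wide values (0.0796), spike-in centring (0.0968), array weights (0.10) and without 6 h replicate 2 (0.0509), and fry gave 0.101. The ribosomal protein list passed as higher (camera adjusted p = 0.0149), though its median was 0.06, its mean 0.16 ± 0.24 (SE over arrays), and 17 of 40 genes had lower values. The adjusted p was 0.588 and 0.650 with an estimated correlation. For the cholesterol list the estimate was 0.01, equal to the preset as rounded, so a clearly larger correlation did not end that call. Random probe sets as bright as the ribosomal list had a median of -0.54, and after quantile normalization the ribosomal median was 0.70; without 6 h replicate 1 or 3 it was -0.01 or -0.04 and the call ended. RPS10, at 1.22 ± 0.24, was the 1 ribosomal gene past the threshold over the list alone, and 0 cholesterol genes were.

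Single values at 24 h lay back toward those before feeding for several genes high at 6 h. Such genes are taken for their high 6 h values and the same 6 h arrays enter here. Noise in those arrays could give part or all of this. HSP70.2 differed from 6 h by -3.73 ± 0.88 and HP by -4.52 ± 1.33; without 6 h replicate 3 these were -2.61 and -2.88, and without 6 h replicate 2 they were -4.81 and -6.47 and both passed the threshold. HSPB1, a small heat shock protein, differed from 6 h by -2.61 ± 0.70 and IL1RN by -1.92 ± 0.37. Other genes were higher at 24 h than at 6 h, with the same 6 h arrays entering. COX5A was at 0.99 ± 0.28, DLD, a subunit of mitochondrial dehydrogenase complexes, at 1.72 ± 0.47 and ACADM, of fatty acid oxidation, at 1.78 ± 0.57. COX5A and DLD had been lower at 6 h than before feeding (-1.14 and -1.13). The DLD mean at 24 h, 1.53, lay above its 0.94 before feeding. By limma 0 probes passed, with 4270 at an unadjusted p under 0.05, 989 by chance and a smallest adjusted p of 0.112; without 6 h replicate 2 the count was 1950. The number of lists was 8 without 24 h replicate 1, against 5.

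Across the 3 times together, the limma F test called 0 of 19783 probes, with 5146 at an unadjusted p under 0.05; without 6 h replicate 2 it called 1637. None was called in the same direction at both 6 h and 24 h against before feeding. The F test count and the shared count were 7 and 5 with quantile normalization, 8 and 5 on the deposited series-wide values and 3387 and 461 with spike-in centring. The changes at the 2 times had a covariance of 0.202 across probes, against a median of 0.0905 in 100 simulations of unchanged groups sharing the same controls, 20 of which were as high. The correlation across probes, which are not independent replicates, was 0.47, against 0.57 simulated. The 3 control arrays cannot be divided, so part of any excess may come from them.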

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

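The tests of T cells against ribosomal protein genes, of scanner gain, and of brightness for ATP synthase and complex I were chosen only after the result was seen, as was the fine match on brightness. In 5 gene lists the change at 24 h differed from the change at 6 h by the camera test with its preset correlation. The median differences were -1.58 for neutrophil markers, -0.79 for monocyte markers, 0.64 for T cell markers, 0.83 for cholesterol genes and 0.06 for ribosomal protein genes. None of the 5 held with an estimated correlation, where adjusted p-values ran from 0.588 to 0.650. Groups of 3 are too small for a test of single outlying arrays.

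Lower T cell and higher neutrophil and monocyte markers at 6 h are the first pattern. Probe brightness was argued against for the T cell list alone: its median lay at percentile 0.02 of 10000 random probe sets matched on mean signal. The neutrophil and monocyte lists had median signal percentiles of 93.4 and 92.7. They were not matched at 6 h, so brightness was not tested for them. All tested probes from the 90th to the 95th percentile of signal had a median of 0.21 at 6 h, against 1.43 and 1.75 for these lists. At the preset correlation no single array made the 3 calls: the largest adjusted p with any 1 array left out was 0.0127 by camera. None of the 3 held with an estimated correlation, so this check covers the preset calls alone. The 6 h levels were uneven, at 1.12, 0.27 and 2.14 for neutrophil and -0.44, 0.05 and -1.20 for T cell markers. A smaller share of all lymphocytes may account for the T cell values, but the immunoglobulin probes, at -0.05 ± 0.27 (SE over arrays), leave this open in both directions. Feeding, handling and time of day, which have no control group, also stay open as untested, beside azide itself.

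Lower ribosomal protein genes are the second pattern, with ATP synthase and complex I beside them at 24 h. Brightness was argued against at 6 h, where 0 of 10000 random probe sets matched on mean signal had a median as low. At 24 h a percentile under 2.5 was set beforehand to argue against brightness, and the ribosomal list lay at 0.17, but that bound was not enough: the matched sets had a median of -0.45 themselves against -0.66, and the call ended on the deposited series-wide values, so brightness may account for much of it and the remainder cannot be told apart from it; an earlier match in 10 coarse bins had given percentile 0. For ATP synthase and complex I the percentiles were 3.75 and 12.5, within what brightness alone gives. T cell markers lay 0.09 ± 0.19 above the ribosomal genes relative to probes of like brightness, against 0.41 ± 0.17 without that step, so a smaller share of T cells stays open. At the preset correlation no single array made the 24 h ribosomal call (largest adjusted p with 1 left out 6.18e-07 by camera). That call did not hold with an estimated correlation, so this check covers the preset call alone.

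The third pattern is that at 24 h the arrays were brighter than the spike-in controls would give, with a median change of 1.00 relative to them. A higher scanner gain would raise the spike-ins too, yet their mean differed by -0.14 ± 0.18 while the 75th percentile differed by 0.86 ± 0.38 on the log2 scale. Without the brightest array, 24 h replicate 3, the median was 0.81, so that array is not the whole cause. The amount of RNA labelled, or of spike-in added, may differ between the groups, or bright signals may be compressed at 24 h, where the brightest 1% of probes had a median of -0.65; no value here decides between these and a change in the blood.

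For the counts of probes, 10 splits of 6 arrays are too few for a share under 0.05. At 6 h the real split gave 5 probes and the highest other 0; for 24 h against before and against 6 h, the real split and the highest other gave 0. Splits at or above the real value, the real one included, numbered 1, 10 and 10 of 10. For lists the real values were 11, 3 and 5 and the highest others 10, 4 and 9, with 1, 4 and 3 splits as large. For the F test and for shared calls the real value was 0, which each of 100 drawn splits reaches by construction, so these splits decide nothing; the highest others were 77 and 22. Why splits that mix the times call probes or lists was not tested.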

How the results depend on the processing

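Array weights and the percentile over probes well above background on all 9 arrays were chosen only after the result was seen; the cause of the differences below was not tested unless said. Over all alternatives, 19 list calls gave 456 values, of which 406 kept direction and side of the threshold, 45 lost the call and 5 turned. A list value turned where the sign of its median or the direction of its test changed. Of the 5, 3 came with spike-in centring, and none of the 19 lists was called in the opposite direction. The 147 gene values gave 3069, of which 2797 kept both, 254 crossed to called and 18 turned. No named gene passed in the main fit, so keeping the side of the threshold meant only staying uncalled. Of the 254, 130 came with array weights and 65 without 6 h replicate 2. Camera with an estimated correlation left 0 lists in each comparison, and fry gave 1 list for 24 h against 6 h, antigen presentation, which is none of the 5 camera calls. The count of 5 probes at 6 h was 8 with quantile normalization and with the series matrix values, and 0 with normexp, no filter, the filter on all 9 arrays, trend and robust, the added percentile, and only the arrays of the 2 groups compared. With one value per gene symbol, 10 of 1580 named genes passed at 6 h, 9 higher and 1 lower; none of the 5 probes has a symbol, so these are other items. Quantile normalization gave 6 probes at 24 h, 7 across the 3 times and 5 shared; series matrix values gave 6, 8 and 5, with 0 lists at 24 h; both these values and normexp gave 3 lists for 24 h against 6 h. Spike-in centring shifted the median change of all probes to 0.28 at 6 h, 1.00 at 24 h and 0.68 between them. It gave 659 probes at 6 h (653 higher, against 5 of 5), 5896 at 24 h (5893 higher), 3387 across the times and 461 shared. Under it the 24 h medians turned to 0.69 for complex I, 0.44 for ATP synthase and 0.35 for ribosomal proteins, as this shift gives. The 24 h changes turned to 0.33 for CST3, 0.02 for CCR7, 0.09 for HBE1 and RPS21, 0.25 for NDUFS5, 0.12 for ND6, 0.21 for COX7A2, 0.13 for ATP5I, 0.37 for ATP5J2, 0.22 for FTH1 and 0.36 for SLA-1, and those against 6 h to 0.03 for NDUFB11, 0.00 for SLC2A1 and 0.10 for PSMC5. SLA-1 at 24 h was also 0.03 with quantile normalization, 0.06 with normexp and 0.04 with series matrix values, where CST3 was 0.00.

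Array weights gave 9889 probes at 6 h, 5445 at 24 h, 5769 for 24 h against 6 h, 11763 across the times and 3179 shared, with 8 lists at 24 h; groupings that mix the times gave up to 13868 with weights estimated anew for each, so these are not read as changes. Leaving out 1 array gave 0 to 2697 probes at 6 h, 0 to 1950 for 24 h against 6 h and 0 to 1637 across the times, each highest without 6 h replicate 2. It gave 2 to 6 lists at 24 h and 4 to 8 for 24 h against 6 h, and the ribosomal median of 24 h against 6 h ran from -0.04 without 6 h replicate 3, through -0.01 without 6 h replicate 1, to 0.26 without 6 h replicate 2. Whether the replicate numbers pair the samples was not settled. Correlations of same-number deviations ran from -0.20 to 0.64, with 5 of 9 over 0.1. In another group, 7 of 9 arrays matched best with their own number. With the number as a replicate block 620 probes were called at 6 h, 537 higher and 83 lower, and the other counts of probes stayed at 0. Signal over background limits the dim probes, of which 23813 were not tested.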

Other observations

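The tests of array weights and of other splits without 6 h replicate 2 were chosen only after the result was seen, as were the genes named here. HP was at -0.84 ± 0.76 before feeding, 4.50 ± 3.62 at 6 h and -0.02 ± 0.20 at 24 h (mean and SD of scaled log2 signal, n = 3). The ferritin heavy chain FTH1 was at 11.22, 11.30 and 10.44, with a change at 24 h of -0.79 ± 0.34 and adjusted p = 0.349 by limma.

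The 6 h arrays differed among themselves. T cell marker levels were -0.44, 0.05 and -1.20 and monocyte marker levels 0.61, 0.25 and 1.55 in replicates 1, 2 and 3, with replicate 2 nearest to the arrays before feeding in both. Ribosomal protein levels in these arrays were -0.53, 0.16 and -0.54. Without replicate 2, limma called 2697 probes at 6 h against before feeding, while the highest of the other 9 splits of those 5 arrays gave 0. These 10 splits are too few for a share under 0.05. Replicate 2 was also taken up because leaving it out gave the highest count, so the splits decide nothing. Each of the 9 arrays was left out in turn by plan, and no reason to exclude this one is known.

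Weighting arrays by their spread gave 9889 probes at 6 h, but this count is not evidence of change. In 99 other groupings of the 9 arrays, which mix the times, weighting, estimated anew for each, gave calls in 48, up to 13868 probes, and 5 reached the real count. Without weights 14 of the same groupings gave calls, at most 176. The weights in the real groups ran from 0.274 for 6 h replicate 2 to 8.27 for the third array before feeding.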
